A study of Mus musculus with 6 samples.

How the data were processed

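Total RNA from mouse colon was extracted with Trizol and a Qiagen kit, 2 µg was amplified and labelled with biotin, and each of the 6 samples was hybridised to 1 Affymetrix array of the mouse 430 2.0 type, per the labels. The deposited values are an intensity per probe set and array, made by the authors with MAS5, for which no version is given in the sources used here. The values are on a linear scale and had already been scaled between arrays: leaving out the lowest and the highest 2% of probe sets, the mean signal was 500.0 in every array. Detection calls, scan dates and the unprocessed array images were not used here. A MAS5 signal is a summary over the probes of a probe set after background subtraction, so values near the low end are dominated by background and ratios of weak signals are unstable.

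The 45101 probe sets were joined to gene symbols and Entrez identifiers with the annotation table of the array. Of these, 34958 carried 1 gene symbol, 932 carried several and 9211 carried none, and 64 were array controls. Gene positions came from the RefSeq table of GRCm38.p6, in which 34754 probe sets were matched by Entrez identifier. Where a gene had several probe sets, the one with the highest mean log2 signal over the 6 arrays was kept, which gave 18193 genes. Genes whose mean log2 signal over the 6 arrays lay above the 40th percentile over genes were tested, which left 10916 genes. A gene near background in most arrays was thus tested only if it was high in the others, which favours genes that differ between arrays. A pseudocount of 18, the 20th percentile of all deposited values, was added before taking log2, so that weak signals are drawn toward each other and large folds against a weak group are limited by it.

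Groups were taken from the sample titles: WT, GPR41 KO and GPR43 KO, with 2 arrays each. A linear model with 1 mean per group was fitted to all 6 arrays with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3. It had 3 residual degrees of freedom, raised to 8.71 by sharing the spread between genes. Comparisons were GPR41 KO against WT, GPR43 KO against WT, GPR43 KO against GPR41 KO, and the mean of both KO groups against WT. Tests were two-sided, and p-values were adjusted with the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Errors given with ± are standard errors (SE) of the limma fit. Replicate numbers do not say that arrays of different groups belong together, so no pairing entered the fit.

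Gene lists for pathways and for the cell types of colon were fixed before the data were examined, as were the comparisons, their tests and all alternatives but 1. The tests of explanations among the additional observations were chosen after the results were seen. Of 44 lists, 39 had at least 5 tested members and were tested with camera in limma with a preset correlation between genes of 0.01, which asks whether members lie higher or lower than the other genes. Estimated correlation and fry, which asks whether the members move one way on balance, were run as alternatives. The count of members past the threshold is given over all genes and adjusted over the list alone. The list called MHC class II genes for short was fixed with class I and other antigen presentation genes as well. A fixed rule set which genes could be named: the 12 largest rises and the 12 largest falls among changed genes whose arrays did not overlap between groups, up to 4 members with the smallest p of each list that passed, the tested members of the list of short-chain fatty acid receptors and transporters, and any gene in a count of 5 or fewer. The text names only a part of the genes that this rule allows, so that each lost or turned value of a named gene could be given. Members of the list of neighbours of the Ffar locus, adipocyte and pancreas genes given among the other observations were chosen after their values were seen.

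The procedure was tested on simulated data with the spread of these arrays: among 10916 genes, 200 were shifted in each of 10 draws. At a log2 shift of 1, 76.8% were recovered with 13.5 false calls per draw, and at a log2 shift of 2, 99.5% were recovered with 14.3 false calls per draw. False calls were thus 8.08% and 6.71% of all calls, above the 5% that the threshold aims at. With no shift, camera called 0.4 lists per draw, and a neutrophil list shifted by -1 was called in 100% of 20 draws. Genes were simulated as independent of each other. These draws therefore do not show how often camera calls lists whose members vary together. The correlation of the fold changes of both KO groups was set against 100 simulated data sets without any effect that share the WT arrays. Because both comparisons use the same WT arrays, it was also computed with 1 WT array for each, an alternative chosen after seeing the data.

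Alternatives covered the pseudocount, a floor in its place, quantile normalization, median centring, the filter on weak genes, the mean over probe sets, all probe sets as the unit, eBayes without trend or with a robust trend, a fit on the compared groups alone, array weights, a replicate block, another threshold and each array left out in turn. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 joined the tables, and matplotlib 3.10.9 drew the figures.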

Results

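Gene expression was measured in colon tissue of C57BL/6 mice harvested 24 h after a rectal injection of ethanol. The 6 arrays fell into 3 genotype groups of 2 arrays each: wild type (WT), GPR41 KO and GPR43 KO. GPR41 (gene Ffar3) and GPR43 (gene Ffar2) are G protein-coupled receptors for short-chain fatty acids, the products of bacterial fermentation in the colon. Colon without ethanol was not analysed here, so each comparison is between genotypes after the injection. The median probe set signal was 94.6 and 94.0 in the WT arrays, 80.9 and 93.9 in the GPR41 KO arrays, and 96.8 and 91.9 in the GPR43 KO arrays. The ratio of 3' to 5' signal of Gapdh, a sign of RNA integrity, ranged from 0.778 to 0.858. The first principal component of the tested genes held 59.6% of the variance and set WT (-24.6 and -44.1) apart from the 4 arrays labelled KO (11.2 to 20.1), of which the library labelled GPR43 KO replicate 1 stood at 11.2. The labels do not say whether the arrays of a group come from separate animals, and the p-values then measure only the spread between these samples. The number of arrays limits the precision: an exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333.

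Ffar2 was low in only 1 of the libraries labelled GPR43 KO. The gene lies on chromosome 7 at 30818031 to 30823775 (GRCm38.p6) and is read by 2 probe sets. The probe set with the higher signal gave 1194 and 1118 in WT, 1857 and 1933 in GPR41 KO, 1598 in the library labelled GPR43 KO replicate 1, and 189.0 in GPR43 KO replicate 2. The library labelled GPR43 KO replicate 1 thus had 1.38 times the WT mean, and GPR43 KO replicate 2 had 16.4% of it. The other probe set gave 840.2 and 756.9 in WT, 1229 and 1345 in GPR41 KO, 1142 in the library labelled GPR43 KO replicate 1 (1.43 times the WT mean) and 76.3 in GPR43 KO replicate 2 (9.56%). In limma the log2 fold change of Ffar2 in GPR43 KO was -1.02 ± 0.72 (SE, n = 2 per group, adjusted p = 0.482). It was -2.50 (adjusted p = 0.000491) without the library labelled GPR43 KO replicate 1 and 0.46 (adjusted p = 0.284) without GPR43 KO replicate 2. Each of these fits leaves 1 array in the group, which is assumed to vary like the other groups. In GPR41 KO the log2 fold change of Ffar2 was 0.70 ± 0.72 (adjusted p = 0.647), and it passed the threshold without the library labelled GPR43 KO replicate 1 (adjusted p = 0.0365) or GPR43 KO replicate 2 (0.0275). The SE of the fit is drawn from the spread in all 3 groups. In the probe set with the higher signal the SD was 53.7 in WT, 53.6 in GPR41 KO and 996.2 in GPR43 KO. The SE of 0.72 for GPR41 KO thus mostly reflects the 2 unlike GPR43 KO arrays, while both GPR41 KO arrays lay above both WT arrays. The deleted part of each allele is not given in the sources used here, and a probe set outside it would check nothing. No probe set carried the symbol Ffar3 in the annotation used, so the GPR41 KO label was not checked.

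**Figure D1:**
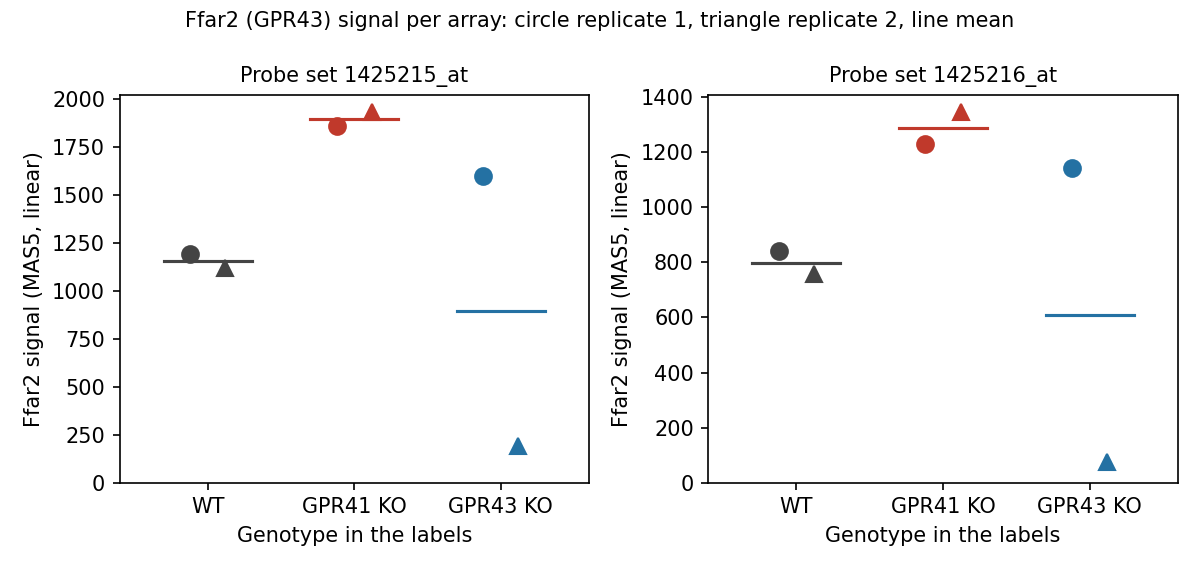
Signal of the 2 Ffar2 probe sets in each of the 6 arrays (MAS5 intensity, linear axis from 0, 1 panel per probe set), with circles for replicate 1, triangles for replicate 2 and a line at the mean of each genotype group. In the probe set with the higher signal, the library labelled GPR43 KO replicate 1 stands at 1598 and GPR43 KO replicate 2 at 189.0.

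Among the receptors, transporters and signalling partners of short-chain fatty acids, Hcar2, a receptor for niacin and butyrate, had the largest change. Its log2 fold change was -4.12 ± 0.61 in GPR41 KO (adjusted p = 0.00633) and -4.59 ± 0.61 in GPR43 KO (adjusted p = 0.00537), with mean signals of 1115 in WT, 45.6 in GPR41 KO and 41.0 in GPR43 KO. The signals in the arrays labelled KO were weak, from 3.78 to 78.3, so the size of these falls depends on the pseudocount. The first of these calls was lost without GPR41 KO replicate 1 (adjusted p = 0.0519). In GPR41 KO, 3 of the 12 tested members fell, 0 rose and 9 did not pass (2 rose and 5 fell adjusted over the list alone). Besides Hcar2 these were the monocarboxylate transporter Slc16a3 (log2 -1.56) and the arrestin Arrb2 (-1.55). The call of Slc16a3 was lost without WT replicate 2 (adjusted p = 0.187), GPR41 KO replicate 1 (0.104) or GPR41 KO replicate 2 (0.172), and that of Arrb2 likewise (0.0559, 0.0951 and 0.0617). In GPR43 KO, with the library labelled GPR43 KO replicate 1 included, 1 of the 12 fell and 11 did not pass (2 rose and 4 fell adjusted over the list alone), with Slc16a3 at -1.22 and Arrb2 at -0.98. The transporters Slc5a8 (1.08 and 0.91) and Slc16a1 (0.24 and 0.18) and the chloride and bicarbonate exchanger Slc26a3 (1.05 and 0.92) did not pass in either group. The list as a whole did not pass in camera (adjusted p = 0.449 and 0.31). Its median in GPR41 KO was 0.05 while its mean was -0.38 and its test pointed down. In the same arrays labelled KO the mean of the neutrophil markers lay between -4.56 and -3.85 against WT. Whether the falls of Hcar2, Slc16a3 and Arrb2 are part of that fall was not tested.

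GPR41 KO colon, set against WT to ask what differs after ethanol when this receptor is missing, had far lower signals of neutrophil and acute inflammation genes. Cxcl2, a chemokine that attracts neutrophils, had a mean signal of 16169 in WT and 39.5 in GPR41 KO, a log2 fold change of -8.10 ± 0.33 (SE, n = 2 per group, adjusted p = 1.2e-05). S100a9 and S100a8, the subunits of calprotectin, fell by 7.35 ± 0.59 and fell by 7.08 ± 0.43 on the log2 scale. Lcn2, which binds bacterial siderophores, fell by 7.05 ± 0.32, the acute phase gene Saa3 fell by 6.79 ± 0.25 and the cytokine Il1b fell by 5.99 ± 0.27. The 12 largest falls also held Hp, Mmp8, Il1r2, Chil3, Ngp and Clec4e, with log2 fold changes from -5.92 to -5.26, and each of the 12 stayed past the threshold whichever array was left out. Because KO signals of these genes are weak, the folds depend on the pseudocount: Cxcl2 in GPR41 KO against WT was at -8.61 with a pseudocount of 1 and at -7.15 with 4 times the 20th percentile. In all, 541 of the 10916 genes changed, 202 higher and 339 lower, and 336 of them changed at least 2-fold (73 higher and 263 lower). The count was 892 without WT replicate 1, 307 without WT replicate 2, 195 without GPR41 KO replicate 1 and 261 without GPR41 KO replicate 2. In 5450 genes (49.9%) the arrays of the groups did not overlap, where chance gives 33.3%. Lower genes were in smaller excess at other cuts: 1006 genes were higher and 1126 lower at an unadjusted limma p under 0.05. With the filter at the 60th percentile, 165 passed as higher and 170 as lower.

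Of the 12 tested neutrophil markers, 11 fell in GPR41 KO, 0 rose and 1 did not pass (11 fell and 1 rose adjusted over the list alone). Their median log2 fold change was -5.26. Of 21 neutrophil markers with a probe set only these 12 lay above the filter, and of 20 inflammatory cytokines only 7. Where KO signals are weak the filter keeps genes that are high in WT, so the tested members are not an unbiased part of these lists. The chemokines of neutrophils and monocytes had a median of -2.73 over 15 members, of which 11 fell and 4 did not pass (12 fell and 1 rose adjusted over the list alone), among them Cxcl5 (-4.42), Ccl2 (-3.82) and Ccl7 (-3.71). Wound repair and matrix remodelling genes had a median of -1.57, with 13 of 22 lower and 9 not past the threshold (16 lower and 1 higher adjusted over the list alone). Examples are the protease inhibitor Timp1 (-4.36), the prostaglandin synthase Ptgs2 (-3.64) and Thbs1 (-2.70). Camera's adjusted p was 6.17e-17 for the neutrophil markers, 3.19e-13 for the chemokines and 3.19e-13 for wound repair, and adjusted p = 0.311 with an estimated correlation for each of them. Of 7 inflammatory cytokines 5 fell and 2 did not pass, the same counts adjusted over the list alone, including Osm (-3.76), Il33 (-2.52) and the antagonist Il1rn (-1.71). Of 17 NF-kB target and feedback genes 5 fell and 12 did not pass (13 fell adjusted over the list alone), including Socs3 (-3.11). Camera's adjusted p was 7.29e-07 and 1.07e-09 for these, and adjusted p = 0.311 with an estimated correlation for both. Macrophage and monocyte markers had a median of -1.16 (adjusted p = 1.22e-10, adjusted p = 0.339 with an estimated correlation). Of these 18, 8 fell and 10 did not pass (13 fell adjusted over the list alone), including Fcer1g (-2.81), Itgam (-2.46), Cd14 (-2.29) and Tyrobp (-2.26). Antimicrobial genes had a median of -0.39 (adjusted p = 0.000122, adjusted p = 0.311 with an estimated correlation), with 7 of 17 lower, 1 higher and 9 not past the threshold (9 lower and 3 higher adjusted over the list alone). S100a8 and S100a9 count in this list and among the neutrophil markers.

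Of 16 cholesterol synthesis genes 9 rose in GPR41 KO, 0 fell and 7 did not pass (16 rose adjusted over the list alone), with a median log2 fold change of 0.82 (adjusted p = 3.32e-13, adjusted p = 0.311 with an estimated correlation). Hmgcs1, which makes the precursor of mevalonate, rose by 1.34 ± 0.17 (adjusted p = 0.00357) and Fdps, farnesyl diphosphate synthase, by 1.31 ± 0.15 (adjusted p = 0.00195). Of the 12 largest rises, 7 passed whichever array was left out: the carbonic anhydrase Car3, a member of the adipocyte list (2.83 ± 0.34, adjusted p = 0.00279), the transporter Slc37a2 (2.76), the proton pump subunit Atp12a (2.64), the enolase Eno3 (2.46), 2210407C18Rik (2.38), Pla2g3 (2.37) and Reg4 (2.23). The other 5 were 2310079G19Rik (2.69), the transglutaminase Tgm3 (2.54), Iglv1 (2.41), Igsf23 (2.30) and the water channel Aqp8 (2.03), and without GPR41 KO replicate 1 they did not pass (adjusted p = 0.058, 0.0629, 0.0941, 0.151 and 0.104). Without GPR41 KO replicate 2 the adjusted p was 0.0763 for Tgm3, 0.0872 for Igsf23 and 0.0716 for Aqp8, and without WT replicate 2 it was 0.0675 for Igsf23. Absorptive colonocyte markers had a median of 0.38 over 25 members, of which 5 rose and 20 did not pass (11 rose adjusted over the list alone). Their adjusted p was 2.31e-05, and adjusted p = 0.311 with an estimated correlation.

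Goblet cell markers had a median of 0.33 (1 of 20 rose and 19 did not pass, 1 rose adjusted over the list alone) and smooth muscle markers of 0.35 (2 of 21 rose and 19 did not pass, 2 rose adjusted over the list alone). Their adjusted p was 4.28e-05 and 3.88e-05, against adjusted p = 0.362 and adjusted p = 0.499 with an estimated correlation. The goblet mean of 0.39 became 0.20 without WT replicate 2 and 0.26 without GPR41 KO replicate 1, and the smooth muscle mean of 0.35 became 0.23 without WT replicate 1 and 0.21 without GPR41 KO replicate 2. Plasma cell markers had a median of 0.47, with 1 of 9 higher and 8 not past the threshold (5 higher adjusted over the list alone; adjusted p = 0.00248, adjusted p = 0.311 with an estimated correlation). Endothelial markers had a median of -0.45, with 1 of 18 lower and 17 not past the threshold (7 lower adjusted over the list alone; adjusted p = 0.000234, adjusted p = 0.362 with an estimated correlation), and their mean of -0.40 became -0.27 without WT replicate 2. Enteric neuron and glia markers had a median of -0.42, with 3 of 17 lower and 14 not past the threshold, 3 lower also adjusted over the list alone (adjusted p = 0.000166, adjusted p = 0.42 with an estimated correlation). In all, 23 of the 39 lists passed, 10 higher and 13 lower, and 0 passed with limma's camera at an estimated correlation (3 at an unadjusted p under 0.05) or with fry (16 at an unadjusted p under 0.05). Of the 23, 14 passed whichever array was left out.

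The other 9 lists each lost their call with at least 1 array left out. Interferon response genes had a median of 0.61 in GPR41 KO (1 of 26 rose, the regulator Irf7, by 1.41, and 25 did not pass, with 1 rise adjusted over the list alone). This list had an adjusted p of 0.00106, and adjusted p = 0.61 with an estimated correlation. Its mean of 0.61 became 1.51 without GPR41 KO replicate 1, -0.30 without GPR41 KO replicate 2 (adjusted p = 0.0784) and 0.33 without WT replicate 1 (0.105). Irf7 was at 0.92 without GPR41 KO replicate 2. The adjusted p of MAPK immediate early genes (median -0.26) was 0.0698 without WT replicate 2 and 0.0745 without GPR41 KO replicate 2, and that of tight junction genes (0.19) was 0.14 without WT replicate 2 and 0.156 without GPR41 KO replicate 1. MHC class II genes (0.41) had 0.0783 and squamous epithelium markers (-1.28) 0.0784 without GPR41 KO replicate 2. T and NK cell markers (0.17) had 0.164, Paneth cell markers (-0.88) 0.154 and proximal colon genes (0.35) 0.105 without WT replicate 1, and these had 0.12, 0.0991 and 0.0784 without GPR41 KO replicate 2. Fibroblast and stromal markers (-0.29) had 0.138 without WT replicate 2 and 0.316 without GPR41 KO replicate 1, and their mean of -0.35 became -0.17 and -0.19 in these fits and -0.53 without WT replicate 1. The Paneth mean of -0.41 became -0.034 without WT replicate 1, -0.029 without GPR41 KO replicate 2, and -0.78 without WT replicate 2 or GPR41 KO replicate 1. Without GPR41 KO replicate 2 the mean of MHC class II genes went from 0.49 to 0.25 and that of T and NK cell markers from 0.64 to 0.38, and without WT replicate 2 that of tight junction genes went from 0.19 to 0.11. With all arrays, the adjusted p of these 8 lists ranged from 0.000452 to 0.0487, and with an estimated correlation from 0.311 to 0.567. Members past the threshold were 5 lower and 1 higher of 24 MAPK genes (8 and 2 adjusted over the list alone), 1 higher of 17 tight junction genes (2), 0 of 10 MHC class II genes (3 higher) and 1 higher of 5 T and NK cell markers (2). They were 2 lower of 5 squamous epithelium markers (3), 2 lower of 5 Paneth cell markers (3), 3 higher of 11 proximal colon genes (3) and 2 lower of 22 fibroblast and stromal markers (6), with the count adjusted over the list alone in parentheses. The called squamous markers were Dmkn (-2.12) and Sbsn (-1.95), and neither call held whichever array was left out. Sbsn lies within 5 Mb of Ffar2, so this list does not measure a cell type apart from the targeted region.

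**Figure D2:**
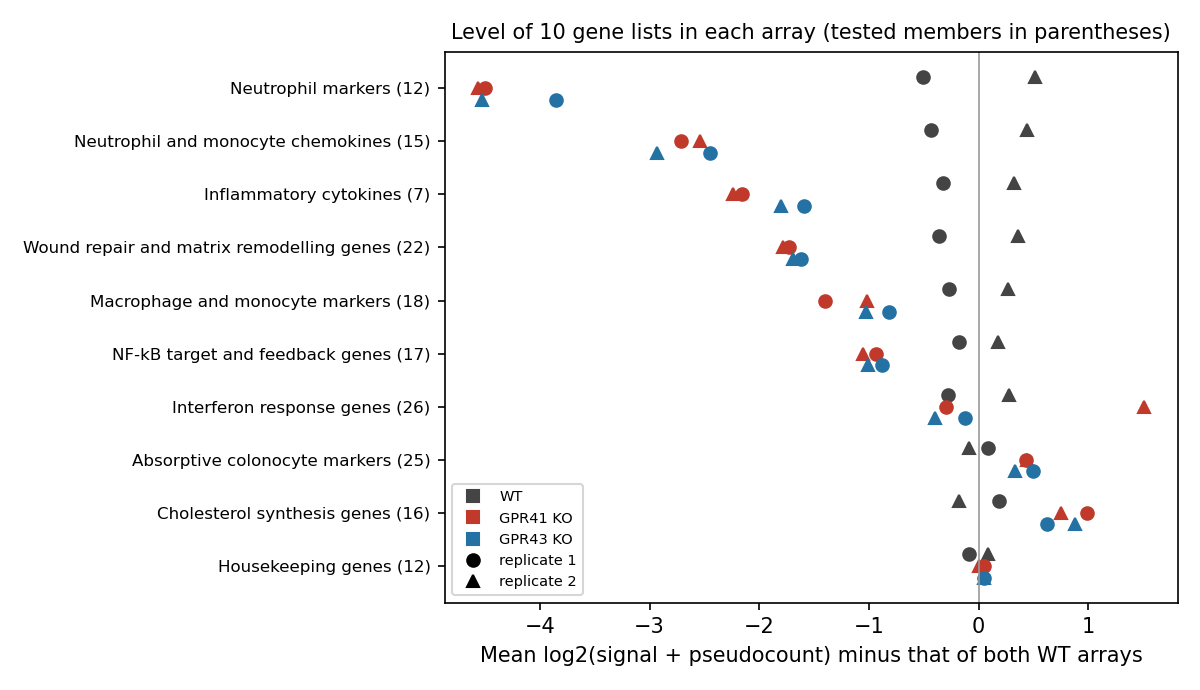
Mean log2(signal + 18) of the tested members of 10 gene lists in each array, minus the mean of both WT arrays; circles are replicate 1 and triangles replicate 2, coloured by group, with the number of members in parentheses. Neutrophil markers lie between -4.56 and -3.85 in the 4 arrays labelled KO, with -3.85 in the library labelled GPR43 KO replicate 1, housekeeping genes between 0.01 and 0.05, and interferon response genes at 1.51 in GPR41 KO replicate 2.

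GPR43 KO colon, taken with the library labelled GPR43 KO replicate 1 in which Ffar2 was not low, had lower signals of neutrophil and acute inflammation genes against WT. Cxcl2 had a mean signal of 33.9 and fell by 8.30 ± 0.33 on the log2 scale (SE, n = 2 per group, adjusted p = 1.94e-05). The log2 fold change was -6.40 ± 0.32 for Lcn2, -6.38 ± 0.59 for S100a9, -6.05 ± 0.65 for Hp, -5.89 ± 0.43 for S100a8, -5.69 ± 0.27 for Il1b and -5.66 ± 0.25 for Saa3, and each of these fell. The 12 largest falls also held Mmp8, Ngp, Il1r2, Clec4e and Fpr2, a formyl peptide receptor, from -5.39 to -4.85, and all 12 passed whichever array was left out. The largest rises were of Eno3 (2.79 ± 0.28, adjusted p = 0.0015), Slc37a2 (2.58), Tgm3 (2.50), the immunoglobulin light chain gene Iglv1 (2.37) and Car3 (2.09). Of the 12 largest rises, only Eno3, Slc37a2, Iglv1 and Car3 passed whichever array was left out. Without GPR43 KO replicate 2 the adjusted p was 0.0872 for Tgm3, 0.0805 for Pla2g3 (2.01), 0.0994 for Reg4 (1.96), 0.108 for Wdtc1 (1.88), 0.166 for Aqp8 (1.83), 0.0616 for 5033404E19Rik (1.78), 0.121 for H2bc22 (1.78) and 0.209 for Ttr (1.76). Without the library labelled GPR43 KO replicate 1 it was 0.0988 for Reg4, 0.11 for Wdtc1, 0.0586 for Aqp8 and 0.0988 for H2bc22. Without WT replicate 2 it was 0.0685 for Reg4 and 0.109 for Ttr, and Aqp8 was at 1.16. Without GPR41 KO replicate 1 or replicate 2 it was 0.0519 or 0.0511 for Aqp8 and 0.0705 or 0.0696 for Ttr. In all, 432 of the 10916 genes changed, 169 higher and 263 lower, and 258 of them at least 2-fold (53 higher and 205 lower). The count was 222 without the library labelled GPR43 KO replicate 1, of which 194 were among the 432, and 129 without GPR43 KO replicate 2, of which 123 were. It was 761 without WT replicate 1 and 244 without WT replicate 2. In 5521 genes (50.6%) the arrays did not overlap between the groups, where chance gives 33.3%. The excess of lower genes depended on the cut: 1190 genes were higher and 991 lower at an unadjusted limma p under 0.05. With the filter at the 60th percentile, 140 passed as higher and 140 as lower.

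In GPR43 KO, with the library labelled GPR43 KO replicate 1 included, 11 of 12 neutrophil markers fell and 1 did not pass, the same counts adjusted over the list alone, with a median of -4.87, and of 15 chemokines 11 fell and 4 did not pass, also adjusted over the list alone, with a median of -2.41. Examples are Chil3 (-4.57), the granulocyte growth factor Csf3 (-4.20), Ccl7 (-4.00) and Ccl2 (-3.91). Wound repair genes had a median of -1.42, with 12 of 22 lower and 10 not past the threshold (13 lower adjusted over the list alone), including Timp1 (-3.89), Ptgs2 (-3.78), Thbs1 (-2.81) and Ereg (-2.53). Camera's adjusted p was 1.33e-17, 2.8e-16 and 1.89e-12, and adjusted p = 0.323 with an estimated correlation for each. Of 7 cytokines 4 fell and 3 did not pass (5 fell and 1 rose adjusted over the list alone), of 17 NF-kB genes 4 fell and 13 did not pass (13 fell adjusted over the list alone), and of 24 MAPK immediate early genes 6 fell and 18 did not pass (11 fell and 1 rose adjusted over the list alone). The medians were -1.43, -0.75 and -0.51, with Il33 at -2.30, Socs3 at -2.63, Ier3 at -2.74, and the phosphatases Dusp5 and Dusp1 at -2.11 and -1.76. Their adjusted p was 0.000264, 9.02e-10 and 6.61e-05, and adjusted p = 0.323 with an estimated correlation for each. Macrophage and monocyte markers had a median of -0.81, with 7 of 18 lower and 11 not past the threshold (9 lower adjusted over the list alone), including Cd14 (-2.03). Their adjusted p was 1.53e-07, and adjusted p = 0.396 with an estimated correlation. Heat shock genes had a median of -0.24, with 3 of 13 lower and 10 not past the threshold (6 lower adjusted over the list alone; adjusted p = 0.000548, adjusted p = 0.323 with an estimated correlation). Antimicrobial genes had a median of 0.01, a mean of -1.21 and a test that pointed down (adjusted p = 0.0117, adjusted p = 0.323 with an estimated correlation), with 5 of 17 lower, 1 higher and 11 not past the threshold (6 lower and 4 higher adjusted over the list alone). That call was lost without GPR43 KO replicate 2 (adjusted p = 0.0561).

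Among the lists that were higher in GPR43 KO, where the library labelled GPR43 KO replicate 1 again enters, cholesterol synthesis had a median of 0.73, with 5 of 16 higher and 11 not past the threshold (15 higher adjusted over the list alone). Fdps rose by 1.09 ± 0.15 (adjusted p = 0.00539), and Hmgcs1 was at 1.06, a call lost without GPR43 KO replicate 2 (adjusted p = 0.117). Goblet cell markers had a median of 0.50 (3 of 20 higher, 17 not past the threshold, 11 higher adjusted over the list alone), smooth muscle markers of 0.52 (3 of 21, 18 and 13) and colonocyte markers of 0.42 (3 of 25, 22 and 7). The adjusted p of these lists was 1.56e-10, 1.2e-07, 9.66e-08 and 7.19e-05, against adjusted p = 0.323, 0.323, 0.396 and 0.323 with an estimated correlation. The goblet mean of 0.56 became 0.37 without WT replicate 2. Plasma cell markers had a median of 0.52 (2 of 9 higher, 7 not past the threshold, 4 higher adjusted over the list alone). MHC class II and antigen presentation genes had a median of 0.48 (1 of 10, 9 and 5). Camera's adjusted p was 0.00715 and 0.00426 for these 2 lists, and adjusted p = 0.323 and 0.458 with an estimated correlation. Squamous epithelium markers had a median of -1.22 (1 of 5 lower, 4 not past the threshold, 3 lower adjusted over the list alone; adjusted p = 0.00211, adjusted p = 0.323 with an estimated correlation). The called squamous marker was Dmkn (-2.59), and the list also holds Sbsn, which lies within 5 Mb of Ffar2. Tight junction genes (median 0.22, 1 of 17 higher and 16 not past the threshold, 1 higher adjusted over the list alone, adjusted p = 0.0408, adjusted p = 0.396 with an estimated correlation) lost their call without WT replicate 2 (0.269), GPR41 KO replicate 1 (0.0546), GPR41 KO replicate 2 (0.0546) or GPR43 KO replicate 2 (0.283). Neuron and glia markers (median -0.29, 2 of 17 lower and 15 not past the threshold, 3 lower adjusted over the list alone, adjusted p = 0.00111, adjusted p = 0.5 with an estimated correlation) lost theirs without GPR43 KO replicate 2 (0.0756), where their mean of -0.37 became -0.19. The tight junction mean of 0.18 became 0.097 without WT replicate 2 and 0.11 without GPR43 KO replicate 2. In all, 18 of the 39 lists passed, 7 higher and 11 lower, 15 of them whichever array was left out, and 0 passed with an estimated correlation (1 at an unadjusted p under 0.05) or with fry (15 at an unadjusted p under 0.05). Interferon response genes, at a median of -0.31, did not pass (adjusted p = 0.219).

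No single gene passed between the KO groups, in a comparison that asks whether the 2 receptor lines differ and that again contains the library labelled GPR43 KO replicate 1. Limma called 0 of 10916 genes, with 596 at an unadjusted p under 0.05 (358 higher and 238 lower in GPR43 KO) and a smallest adjusted p of 0.612. The chaperone genes Hspa1a, Hspa1b and Hsph1 were at -1.20 ± 0.20, -1.02 ± 0.15 and -0.81 ± 0.15 (SE, n = 2 per group, adjusted p = 0.612 for each), and the antimicrobial genes Reg3b and Reg3g at 1.19 ± 0.38 and 1.12 ± 0.34. Ffar2 was at -1.73 ± 0.72 (adjusted p = 0.87). Leaving out 1 array brought up to 3 genes past the threshold. These were the adaptor Bcar1 (2.02) without WT replicate 1 (adjusted p = 0.00596) or WT replicate 2 (0.00442), and the interferon-induced genes Ddx60 (-3.14, adjusted p = 0.0213) and Oasl2 (-3.23, 0.0213) with Lgals9 (-1.66, 0.0254) without GPR41 KO replicate 1. They were Ffar2 (-3.21, adjusted p = 0.000894) and the peroxidase Lpo (2.50, 0.00126) without the library labelled GPR43 KO replicate 1, and Apoc2 (-2.03, 0.0283), Igsf23 (-2.23, 0.0283) and Tnfsf13os (-4.02, 0.00238) without GPR43 KO replicate 2. Arrays did not overlap between the groups in 4128 genes (37.8%), where chance gives 33.3%.

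At the level of lists, 13 of 39 passed in camera between the KO groups, 7 higher and 6 lower in GPR43 KO with the library labelled GPR43 KO replicate 1 included, although 0 of their members passed over all genes. With limma's camera at an estimated correlation 0 lists passed (adjusted p from 0.659 to 0.881 over the 13, 2 of the 39 at an unadjusted p under 0.05), and with fry 0 (1 at an unadjusted p under 0.05). The call held whichever array was left out for heat shock genes (median -0.23, adjusted p = 1.63e-08, 6 of 13 lower adjusted over the list alone), MAPK immediate early genes (-0.16, 0.000232), adipocyte markers (-0.44, 0.000121), inflammatory cytokines (0.36, 0.00172) and endothelial markers (0.27, 0.000243). Adipocyte markers had a mean of -0.38, and -0.24 without GPR43 KO replicate 2. The interferon response genes were lower by a median of -0.94 (adjusted p = 2.89e-12), with a mean of -0.87 that became -1.77 without GPR41 KO replicate 1 and 0.04 without GPR41 KO replicate 2 (adjusted p = 0.77). Without GPR41 KO replicate 1 the adjusted p was 0.842 for cholesterol synthesis, 0.13 for endoplasmic reticulum stress, 0.672 for macrophage, 0.955 for smooth muscle and 0.235 for fibroblast markers. Without the library labelled GPR43 KO replicate 1 it was 0.956 for cholesterol synthesis, 0.0746 for antimicrobial genes, 0.098 for macrophage, 0.443 for goblet and 0.956 for smooth muscle markers. Without GPR41 KO replicate 2 it was 0.787 for goblet cell markers, and without GPR43 KO replicate 2 it was 0.0639 for endoplasmic reticulum stress genes. In the fits that lost a call the list means lay between -0.074 and 0.19. Means that stayed past the threshold but moved by more than 1.5 times were, without GPR41 KO replicate 2, those of antimicrobial genes (0.51 to 0.34), cholesterol synthesis (-0.11 to -0.23), endoplasmic reticulum stress (-0.15 to -0.22), macrophage (0.29 to 0.48), smooth muscle (0.14 to 0.28) and fibroblast markers (0.31 to 0.47). Without GPR43 KO replicate 2 the mean was 0.84 for antimicrobial genes, -0.24 for cholesterol synthesis, 0.28 for goblet and 0.29 for smooth muscle markers, and without GPR41 KO replicate 1 it was 0.31 for goblet cell markers, from 0.18.

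The mean of both KO groups against WT, with 4 KO arrays that include the library labelled GPR43 KO replicate 1, shows the genes that differ from WT on average over both lines. Cxcl2 fell by 8.20 ± 0.28 on the log2 scale (SE, 4 arrays against 2, adjusted p = 3.11e-06), S100a9 fell by 6.87 ± 0.51, Lcn2 fell by 6.72 ± 0.27, Saa3 fell by 6.22 ± 0.21 and Il1b fell by 5.84 ± 0.24. Eno3 rose by 2.62 ± 0.24 (adjusted p = 0.000615) and Car3 by 2.46 ± 0.30 (adjusted p = 0.00204). Neutrophil markers had a median of -5.01 (11 of 12 fell, 1 did not pass, 11 fell and 1 rose adjusted over the list alone) and chemokines of -2.57 (11 of 15 fell, 4 did not pass, 12 fell adjusted over the list alone). Cholesterol synthesis genes had a median of 0.78 (10 of 16 rose, 6 did not pass, 16 rose adjusted over the list alone), including Fdps (1.20) and Hmgcs1 (1.20), and colonocyte markers of 0.44 (6 of 25 rose, 19 did not pass, 13 rose adjusted over the list alone). Camera's adjusted p was 7.49e-17, 2.23e-14, 2.21e-12 and 2.09e-05, and adjusted p = 0.305 with an estimated correlation for each of the 4. Of 39 lists, 19 passed with camera, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 13 with fry. In all, 763 genes changed, 349 higher and 414 lower, and 342 of them at least 2-fold (76 higher and 266 lower). The count was 355 without WT replicate 2, 457 without GPR41 KO replicate 1, 468 without GPR41 KO replicate 2 and 476 without GPR43 KO replicate 2. Arrays did not overlap in 3535 genes (32.4%), where chance gives 13.3%. The balance of directions depended on the cut: 1294 genes were higher and 1181 lower at an unadjusted limma p under 0.05. With the filter at the 60th percentile, 287 passed as higher and 227 as lower.

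Genes called in both KO groups moved the same way. Of 636 genes called in either comparison with WT, 337 were called in both in the same direction. Of these, 220 were lower in both, where independent lists share 8.17 and simulated data without effect share 0.1, and the rest were higher in both, where independent lists share 3.13 and simulated data 0.02. Neither number measures how alike the KO groups are. Simulated data without effect hold no changed genes to share, and the count for independent lists leaves out that both comparisons use the same WT arrays. There were 0 genes called in opposite directions by limma, and at an unadjusted p under 0.05 in both comparisons there were 4, beside 1363 in the same direction. Across the 10916 genes, which are not independent replicates, the log2 fold changes of the KO groups had a Pearson r of 0.877 and a Spearman rho of 0.739, against 0.499 and 0.472 in simulated data without effect that share the WT arrays. The covariance was 0.230 against 0.0237, a difference of 0.206. In a test chosen after the results were seen, each comparison was given 1 WT array of its own. The Pearson r was 0.683 with WT replicate 1 for GPR41 KO and WT replicate 2 for GPR43 KO and 0.658 the other way round, and the covariance was 0.197 and 0.190, against a simulated r of -0.0012 and 0.0014. The library labelled GPR43 KO replicate 1 enters on the GPR43 KO side of all these values. Simulated genes vary independently, so a simulated r near 0 was fixed in advance for separate WT arrays. A difference common to both WT arrays still enters both comparisons, whatever its source.

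**Figure D3:**
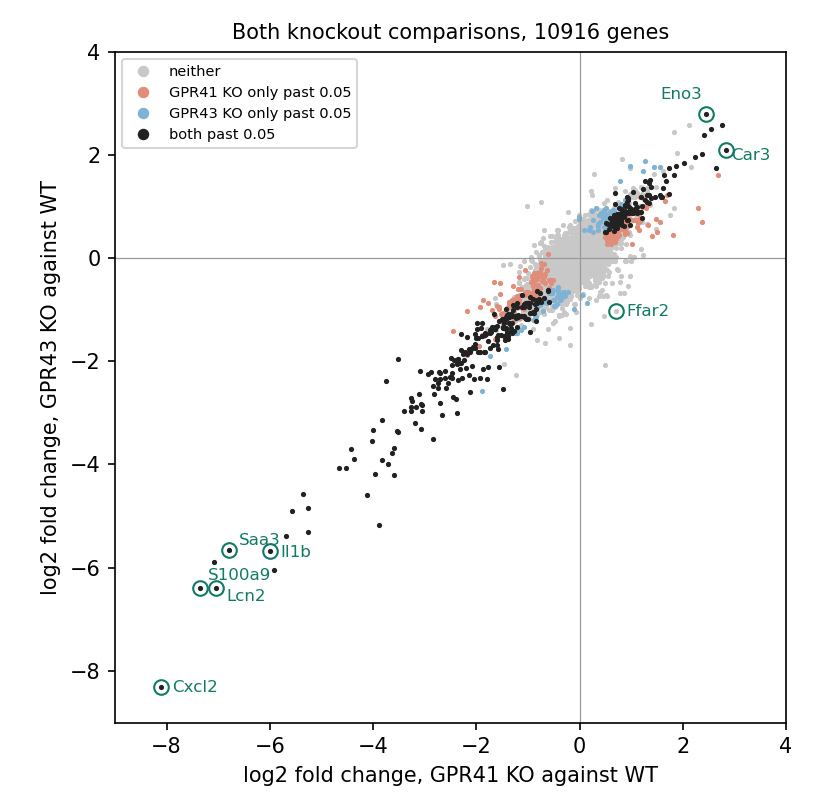
Log2 fold change against WT in GPR41 KO (horizontal axis) and GPR43 KO (vertical axis) of 10916 genes, 1 point per gene, black where called in both comparisons, red or blue where called in GPR41 KO or GPR43 KO alone and grey elsewhere, with a few genes circled and named. Of the 337 genes called in both in the same direction, 220 lie at the lower left and the rest at the upper right, and Cxcl2 lies lowest.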

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

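All tests of explanations in this part were chosen after the results were seen; the list differences between the KO groups were planned. Camera's test of the difference between GPR43 KO and GPR41 KO singled out 13 lists, for which the median log2 differences were: inflammatory cytokines 0.36, MAPK immediate early genes -0.16, interferon response genes -0.94, antimicrobial genes 0.45, cholesterol synthesis -0.13, endoplasmic reticulum stress -0.14, heat shock -0.23, macrophage and monocyte markers 0.32, goblet cell markers 0.16, smooth muscle markers 0.18, fibroblast and stromal markers 0.28, endothelial markers 0.27 and adipocyte markers -0.44. Each of them includes the library labelled GPR43 KO replicate 1, 0 of them passed with an estimated correlation or with fry, and 8 of the 13 lost the call when 1 array was left out. Among 3662 tested probe sets without a single gene symbol, which entered no comparison of genes, 18 were higher in GPR41 KO than in WT and 13 were higher in GPR43 KO, beside 38 and 29 that were lower.

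The first pattern is the Ffar2 signal of the library labelled GPR43 KO replicate 1, at 1.38 and 1.43 times the WT mean, while GPR43 KO replicate 2 had 16.4% and 9.56%. An exchange of labels with a WT or GPR41 KO array needs 1 of those arrays to be low, and the lowest of the 4 had 94.78% of the WT mean. A transcript left by the disrupted allele would show in both KO arrays, which differed by 2.964 and 3.62 on the log2 scale in the probe sets, and an animal with the response of the WT animals would have neutrophil markers near WT, whereas their mean was -3.851 from it. Genes within 5 Mb of Ffar2 sided with WT in this library in 5 of 98 cases against 245 of 10800 elsewhere, an odds ratio of 2.316 (one-sided Fisher exact p = 0.0746, adjusted p = 0.298 over the 4 KO arrays), which leaves open a WT haplotype around Ffar2. A candidate explanation is an animal, possibly from the GPR41 line or from outside the 6 samples, whose Ffar2 gene was intact, and with no probe set for Ffar3 this was not tested.

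The second pattern is the fall of inflammatory genes in all 4 arrays labelled KO against both WT arrays, including the library labelled GPR43 KO replicate 1, where the neutrophil mean of -3.851 goes with an Ffar2 signal of 1.38 and 1.43 times the WT mean. Array scaling, or a few bright genes setting the scale, would lower housekeeping genes too, and their median was 0.0844 (SD 0.21). The nearest of fibroblast, endothelial and smooth muscle medians lay 4.665 above the neutrophil median on the log2 scale, so these layers did not share the neutrophil fall. A smaller difference in the share of tissue layers would also leave these medians far above the neutrophil median. The comparison therefore cannot exclude such a difference. The labels give 0 batch columns, so a harvest, labelling or array batch that coincides with genotype cannot be told apart from genotype. The 15 splits of the 6 arrays into 2 and 4 are too few for a share under 0.05. They were fitted in limma with 2 group means in place of the 3 that gave 763 genes. Only 1 of them, the real one, reached its 853 genes, and the highest of the others gave 0. Every other split puts WT and KO arrays into the same group, so their difference enters the spread and lowers the count. The 0 therefore lends no weight to the grouping. An effect of genotype, of litter or cage, or of how far each animal had responded to ethanol could each account for the pattern, and they stay open and untested, but loss of Ffar2 transcript was not seen in the library labelled GPR43 KO replicate 1.

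The third pattern is the interferon response in GPR41 KO replicate 2 alone, where 17 of 26 members lay at least 1 above all other 5 arrays on the log2 scale and their median deviation was 1.62. Scaling of this array would shift all genes, and the median deviation of all tested genes was -0.00371. More immune cells in the tissue piece would raise a list of immune cell markers as much, and the highest of 5 such lists, that of T and NK cells, deviated by 0.423. No biological explanation was tested, since the labels describe this sample only by its genotype, which GPR41 KO replicate 1 shares.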

How the results depend on the processing

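All alternatives were planned except the split of the WT arrays, which was chosen after seeing the data, and where 1 array is left out the lone sample is assumed to vary like the other groups. Over the alternatives other than leaving out an array, called genes named in the text kept direction and call in 1515 cases and lost the call in 90, and lists did so in 420 and 160 and turned in 4. Fewer genes passed with the filter at the 60th percentile (335 in GPR41 KO, 280 in GPR43 KO), which tests fewer genes, and without the eBayes trend (360, 217, and 485 for the mean of both KO groups), for which the cause was not tested. An unadjusted p under 0.01 with a 2-fold change gave 20 genes between the KO groups and 365 for the mean of both, where p alone gives 109 before the fold is asked for, all probe sets gave 1 (a probe set of Ighm) and the 2 groups alone gave 1 (Bcar1). Lists passing fell to 0 in all 4 comparisons with an estimated correlation and to 0 with fry in the first 3. The former alternative only replaces the preset correlation of 0.01 by an estimated one, so the list calls and their small p-values depend on that preset. For fry the cause was not tested. The correlation of KO fold changes was 0.758 without a filter, which adds weak genes, and 0.683 and 0.658 with 1 WT array for each comparison. That split removes the noise of a shared array, but not what both WT arrays have in common, and leaves 1 array as the control. Leaving out 1 array gave 195 to 892 genes in GPR41 KO, 129 to 761 in GPR43 KO, 0 to 3 between them and 355 to 1009 for the mean of both. It gave a correlation of 0.813 to 0.913, an Ffar2 log2 fold change of 0.66 to 0.75 in GPR41 KO and of -2.50 to 0.46 in GPR43 KO. Directions turned, with the cause not tested, for lists whose mean ranged over these fits from -0.30 to 1.51 (interferon, GPR41 KO) and, between the KO groups, from -1.77 to 0.036 (interferon), -0.24 to 0.015 (cholesterol synthesis, also 0.0034 without GPR41 KO replicate 1) and -0.012 to 0.29 (smooth muscle). The mean of Paneth cell markers was 0.0021 in GPR41 KO and 0.019 in the mean of both without a filter, 0.092 and 0.17 with the mean of probe sets, and -0.66 to 0.081 over the fits in the mean of both. Of uncalled genes, Slc16a1 ranged from -0.016 to 0.50 in GPR41 KO (-0.041 with the mean of probe sets) and -0.076 to 0.44 in GPR43 KO (-0.019 without GPR43 KO replicate 2), Gnaq from -0.042 to 0.35 in both, and Arrb1 from -0.17 to 0.061 in GPR41 KO. Between the KO groups, Ddx60 ranged from -3.14 to 0.14, Oasl2 from -3.23 to 0.042 and Lpo from -0.34 to 2.50. With a replicate block, for which no label gives a reason, 401, 295, 0 and 550 genes and 21, 16, 12 and 19 lists passed, and the differences of replicate 1 from replicate 2 correlated between groups at 0.107, -0.271 and -0.0537. Probe sets of Ffar3 gave no value, so that alternative was not run. Weak signals near background limit the folds of genes that are nearly silent in 1 group, and genes under the filter were not tested. Among 74 other probe sets of called named genes with a mean signal above 100, 0 were opposite in sign.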

Other observations

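The values in this part were chosen after they were seen, apart from the fixed lists and their tests. Some pancreatic digestive enzyme genes were high in WT replicate 1 alone. Of 13 exocrine pancreas genes with a probe set, 10 were highest in WT replicate 1 and 3 in another array. In WT replicate 1 the signal was 404.4 for Cpb1, 491.8 for Cpa1, 1120 for Ctrb1, 580.0 for Cela2a and 315.8 for Pnliprp1, and the highest of the other arrays had 6.60, 11.9, 57.9, 33.1 and 27.1. These other signals lie near background, where the 20th percentile of all values is 18, so no fold is given. These encode carboxypeptidases, a chymotrypsinogen, an elastase and a lipase-related protein. The 3 that were higher elsewhere were Cela1, Zg16 and Clps, with 0.604, 0.590 and 0.437 times the signal of the highest other array in WT replicate 1. None of the 5 first named had a mean log2 signal above the filter, so they entered no test. The fixed list, with 5 members tested, had a median of 0.33 in the mean of both KO groups against WT (adjusted p = 0.395).

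Scd1 and Fabp4, members of the adipocyte list like Car3, changed in opposite directions in both KO groups, the library labelled GPR43 KO replicate 1 included. Scd1, the stearoyl-CoA desaturase, rose by 1.73 ± 0.14 in GPR41 KO (adjusted p = 0.000614) and by 1.25 ± 0.14 in GPR43 KO (adjusted p = 0.00252), and both calls held whichever array was left out. Fabp4, a fatty acid binding protein of adipocytes and macrophages, was at -0.89 in GPR41 KO and -1.05 in GPR43 KO. Its call in GPR41 KO was lost without WT replicate 2 (adjusted p = 0.0611), GPR41 KO replicate 1 (0.104) or GPR41 KO replicate 2 (0.0527), and that in GPR43 KO without GPR43 KO replicate 2 (0.0632). The adipocyte list as a whole did not pass against WT in GPR41 KO (adjusted p = 0.0863; 3 of 12 rose, 2 fell and 7 did not pass) or GPR43 KO (adjusted p = 0.932; 2 rose, 1 fell and 9 did not pass).

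Genes near Ffar2 on chromosome 7, where the genes of both receptors lie, were tested as a list. Of 26 tested neighbours, 1 rose, 4 fell and 21 did not pass in GPR41 KO (1 rose and 5 fell adjusted over the list alone), and 1 rose, 3 fell and 22 did not pass in GPR43 KO (2 rose and 4 fell adjusted over the list alone). The list did not pass (adjusted p = 0.0863 and 0.224). Fxyd5, a regulator of the sodium pump, was at -1.83 in GPR41 KO and -1.45 in GPR43 KO, a call lost in the latter without GPR43 KO replicate 2 (adjusted p = 0.0703). Tyrobp, which is also a macrophage marker, was at -2.26 and -1.86, a call lost in the latter when GPR43 KO replicate 2 was left out. Cox7a1 rose, at 1.26 in GPR41 KO and 1.12 in GPR43 KO, and neither call held whichever array was left out.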
